A study of Mus musculus with 49 samples.

How the data were processed

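The samples were male germ cells of C57BL/6 mice at 4 stages, per the labels. Spermatogonia sorted for Thy1 or for c-Kit came from wild-type testes at postnatal day 7. Pachytene spermatocytes (PS) and round spermatids (RS) came from adult wild-type (WT) and Scml2 knockout (KO) testes. Scml2 encodes a Polycomb group protein of the germline. Of the 49 samples, 47 were peak lists from chromatin immunoprecipitation with sequencing (ChIP-seq) and 2 were RNA-seq tables. The lists comprised 15 of H3K27me3, 11 of H3K4me2, 11 of H3K4me3 and 10 of input chromatin. H3K27me3 marks genes silenced by Polycomb, H3K4me3 marks active or poised promoters and H3K4me2 marks promoters and enhancers. Each group had 2 numbered libraries per mark, except the c-Kit+ cells, with 1 per mark. H3K27me3 in PS and RS also had 1 library per genotype labelled native. The ATAC-seq named in the series design was not analysed here.

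Regions had been called separately for each library, since each list belongs to 1 sample. The submitters' processing notes name STAR 2.4.2a, Bowtie, MACS2 and the builds mm10 and hg19, with no role for any of them. The settings of the peak calling are not given in the sources used here. Per the file headers, each region carries a pileup, a signal of stacked fragments. Per the file headers, it also carries the −log10 of its p-value and q-value and a fold enrichment over a background. These values are the authors' own and were used to rank, filter or describe regions within a list. The exception is a background level compared between lists as an indirect measure of depth, the most frequent value of (pileup + 1) / fold − 1 over the regions of a list. In 31 lists over 99% of rows lay at this value, so their fold was in effect over 1 background for the whole list. In the numbered H3K27me3 lists 79.3% to 94.2% of rows did. A given fold therefore need not mean the same in both kinds of list. The 15 H3K27me3 lists and 1 H3K4me3 list, the second WT list of PS, gave regions without summits, while the other lists gave summits. In the native WT list of PS the 4 value columns were identical, so only its positions were used. Per the file headers, the RNA tables hold read counts per RefSeq gene model and RPKM computed by the authors. The number of reads behind each peak list is unknown, so no interval for counting error is given for them.

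A promoter was the 1 kb on each side of the transcription start of a gene model in the series' own RNA tables. It was called marked when a deposited region overlapped it by at least 1 bp. The 26049 gene models gave 23335 gene symbols, of which 1011 lay on the X chromosome and 22266 on autosomes. For the 2050 symbols with several models, a mark at any model counted. By accession, 25577 models matched a gene of the GRCm38.p6 annotation, and 24488 of them (95.7%) lay inside that gene, so positions are given as mm10. The promoter share is the percentage of the 23335 genes with a mark. A promoter was called bivalent when it had H3K27me3 and lay among the promoters with H3K4me3 in both libraries of the stage and genotype. For the single c-Kit+ library, 1 H3K4me3 list was used. A bivalent call does not show that both marks lay in the same cells. The X chromosome was compared with autosomes, and developmental genes with other autosomal genes, by a log2 odds ratio within each library, with 0.5 added to each cell.

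Before the data were examined, the groups, the tests, the alternatives, the rule for named genes and 13 gene lists were fixed. The lists and the members found among the gene models were Hox genes (39 of 39), other developmental transcription factors (170 of 170) and developmental signalling genes (100 of 100). Germ cell lists were spermatogonial genes (49 of 50), meiotic genes (58 of 67) and spermatid genes (81 of 83). Lists for other cells were Sertoli cell markers (20 of 20) and Leydig, peritubular, vascular and blood cell markers (29 of 31). The remaining lists were housekeeping genes (70 of 72), Polycomb genes (35 of 36), olfactory receptor genes (1088 of 1088), Rhox genes (31 of 31) and keratin genes (52 of 52). The first 3 lists together are called developmental genes (309).

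Genotypes were compared with two-sided exact permutation tests in which genotype labels were permuted among libraries of the same stage and preparation. The statistic was the KO mean minus the WT mean, averaged over stages and preparations. For H3K27me3 this gave 144 labelings and a smallest possible p of 0.0139, and for H3K4me3 or H3K4me2 36 labelings and a smallest possible p of 0.0556. Gene lists were adjusted by the Benjamini-Hochberg method. A change of effect between stages was tested by permuting the same labels. No test was made per gene: promoters marked in every WT and no KO library were counted. Tests of the lists between spermatogonia and later stages, and of H3K4me3 on the X chromosome, were added after the data were examined. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

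Named genes followed a fixed rule. For H3K27me3 in each stage, genes marked in every library of one genotype and none of the other were taken, members of the fixed lists first, then by the lowest fold enrichment over the libraries. Up to 15 were taken in each direction. For H3K4me3 and H3K4me2 up to 6 were taken, and for stages up to 10 list members. In the c-Kit+ RNA the 10 bivalent genes with the highest mean RPKM and up to 4 members per list were taken. Each list gave up to 4 examples, and Scml2 was read in every library.

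RNA levels were compared between promoter classes as medians of log2(RPKM + 1), a scale that understates differences among low genes. The alternatives tried were a window of 2.5 kb, an overlap of 500 bp, regions with a −log10 q of at least 5 or a fold of at least 4, and the same number of strongest regions from each list. Further alternatives left out regions called in WT input, each library in turn, the native libraries or lists of under 1000 regions, or used the replicate number as a block. For RNA they were a pseudocount of 0.1 and a minimum RPKM of 0.1. Input lists entered no comparison of marks except as that filter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The promoter assignment and the permutation test were tested on simulated data with the labels of the 12 H3K27me3 libraries and the 23335 genes. All 200 simulated promoters were recovered (100%), with 0 mismatches. In 400 simulations without a genotype effect 5.75% fell below the threshold of 0.05, and with a shift of 3 SD 98.5% did. Simulated values had 1 spread for all libraries. The SD of the real promoter shares ran from 0.791 points in the numbered WT libraries of PS to 17.3 in the numbered KO libraries of RS. The 98.5% is therefore not the power for the difference observed here.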

Results

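The series addressed how SCML2 shapes bivalent domains, promoters with both H3K4me3 and H3K27me3, during spermatogenesis. The histone marks H3K27me3, H3K4me3 and H3K4me2 and input chromatin were profiled in Thy1+ and c-Kit+ spermatogonia, pachytene spermatocytes (PS) and round spermatids (RS), the last 2 stages with and without Scml2. The H3K27me3 lists held between 3353 regions, in the second numbered KO library of RS, and 185773, in the native WT library of RS. H3K4me3 lists held 23045 to 77112 regions. H3K4me2 lists held 32087 to 129717 regions, apart from 3 short ones with 1002 (PS WT 2), 2 (RS WT 2) and 73 (RS KO 2). The 2 RNA libraries of c-Kit+ cells held 13616281 and 14460973 counts.

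The promoter of Scml2 itself (NM_133194, chromosome X, 161162772 to 161258213, plus strand) carried H3K4me3 in every library of every stage, the KO libraries included. It carried H3K27me3 in no library. H3K4me2 was called there in both Thy1+ libraries, in the c-Kit+ library, in PS WT 1 and in RS KO 1, and in no PS KO library. In c-Kit+ WT cells Scml2 RNA reached 55.8 and 60.2 RPKM. The deleted part of the gene is not given in the sources used here, so marks at its promoter do not check the genotype labels.

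In WT cells H3K27me3 lay over the promoters of developmental regulators at every stage. Hox genes, which pattern the body axis, were marked at 96.2% ± 5.44 (SD, n = 2) of members in Thy1+ cells, 93.6% ± 1.81 (n = 2) in PS and 96.2% ± 5.44 (n = 2) in RS. The other developmental transcription factors stood at 93.5%, 98.8% and 98.5% in the same order, with Otx1, a regulator of forebrain development, marked in every WT library of these stages. Housekeeping genes stood at 0%, 0% and 5%. Rhox genes, X-linked homeobox genes of the reproductive tract, stood at 1.61% in Thy1+ cells and 0% in PS and RS.

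Individual regulators were called in different stages. Bmi1 and Cbx7, which encode subunits of Polycomb repressive complex 1, carried H3K27me3 in both Thy1+ libraries and neither numbered WT library of PS, as did Hoxa4 and the X-linked genes Esx1 and Sox3. In RS, Bmi1, Hoxa4 and Sox3 were called in WT library 1 and not in WT library 2, and Cbx7 and Esx1 in neither. These calls were not tested per gene. Meis1, a Hox cofactor, showed the opposite, with the authors' fold at 8.38 and 11.8 in the 2 PS lists, 10.9 and 7.42 in the 2 RS lists, and no call in Thy1+ cells. Stra8 and Sohlh1, which act in the entry into meiosis and in spermatogonial differentiation, were likewise called in PS and RS but not in Thy1+ cells, as was Fshr, the Sertoli cell receptor for follicle-stimulating hormone. Across all genes, 126 promoters were marked in both Thy1+ and neither PS library and 1094 the other way, and for RS the counts were 52 and 1060. Thy1+ library 2 marked 2117 promoters in all, which caps the Thy1+ counts. Both Thy1+ lists shared 2096 promoters, against 5086 for PS and 4865 for RS. With 2 libraries against 2, a promoter marked in 2 of the 4 by chance alone divides along the labels in 1 of 3 cases.

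The promoter share of H3K27me3 was 17.7% ± 12.2 (SD, n = 2) in Thy1+ cells, 14.5% in the single c-Kit+ library, 24.0% ± 0.791 (n = 2) in PS and 27.5% ± 9.12 (n = 2) in RS. RS exceeded Thy1+ by 9.83 points, less than the pooled SD of 10.8. An exact two-sided permutation test of 2 against 2 cannot go below p = 0.333. The difference was 18.4 points without Thy1+ library 1, 1.21 without Thy1+ library 2, 3.38 without RS library 1 and 16.3 without RS library 2.

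H3K4me3 at spermatid and meiotic genes was called more often in later stages. Spermatid genes carried it at 33.3% ± 4.28 (SD, n = 3) of promoters in spermatogonia and at 100% ± 0 (n = 4) in WT PS and RS. Odf3 and Theg, genes of the sperm tail and of spermatids, were marked in both PS and neither Thy1+ library, and Tssk1, Tssk2 and Acr, which encode 2 testis-specific kinases and the acrosomal protease acrosin, in both RS and neither Thy1+ library. Meiotic genes stood at 63.8% ± 13.8 (n = 3) and 95.7% ± 0.995 (n = 4), with Spo11, the enzyme of meiotic DNA breaks, and Tex12, of the synaptonemal complex, among those first called in PS. Spermatogonial genes stood at 79.6% ± 11.4 and 90.3% ± 3.06, with overlapping libraries (exact permutation p = 0.0857). Rhox genes stood at 3.23% ± 3.23 and 37.9% ± 8.48, and X-linked promoters at 47.4% ± 4.36 and 63.5% ± 2.63. Cdh5, Acta2, Tek, Ptprc and Csf1r, markers of vessels, peritubular cells and blood, had H3K4me3 in both Thy1+ libraries and neither PS library, and the Leydig, peritubular, vascular and blood cell list stood at 44.8% ± 13.8 and 29.3% ± 7.18.

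The exact two-sided permutation p was 0.0286, the smallest that 35 splits allow, for spermatid, meiotic, Polycomb, Rhox and olfactory receptor genes, for X-linked promoters and for all promoters (62.4% and 68.6%). Adjusted over the 15 groups of promoters tested each was 0.0612, so none passed. For H3K27me3 no group passed, and the smallest exact p was 0.0857, for Sertoli cell markers (45.0% in spermatogonia and 72.5% later) and for developmental transcription factors (94.1% and 98.7%). Age differed with stage, since spermatogonia came from young and later cells from adult testes. So did the length of the H3K4me3 lists, with 23045 to 30216 regions in spermatogonia and 38727 to 77112 in WT PS and RS. Equal numbers of regions were not tried for these tests.

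The main question was what the loss of Scml2 did to H3K27me3 at promoters. The mean marked share was lower in KO than in WT in each stage and preparation. In PS it was 24.0% ± 0.791 (SD, n = 2) in the numbered WT and 17.3% ± 7.37 (n = 2) in the numbered KO libraries, and 34.7% against 19.9% in the native ones. In RS it was 27.5% ± 9.12 (n = 2) against 17.2% ± 17.3 (n = 2), and 41.8% against 27.3%. The KO mean lay −11.6 points from WT, with an exact two-sided permutation p of 0.0556 over 12 libraries, which misses 0.05 (smallest possible 0.0139). The effect was −10.8 points in PS and −12.4 in RS, and the test of that difference gave an exact permutation p of 0.917.

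The KO libraries of RS weighed on this value. The first numbered KO library of RS stood at 29.4% and the second at 4.97%. Without the first the difference was −14.6 points (exact permutation p = 0.0139), and without the second −8.53 (exact permutation p = 0.167). The lower mean of the numbered RS libraries in KO rests on the second, since the first lies above the WT mean of 27.5%. With the same number of strongest regions from each list the difference was −1.60 (exact permutation p = 0.667). In the KO input lists, 27.7% to 60.8% of promoters overlapped a region, against at most 7.65% in WT input.

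**Figure D1:**
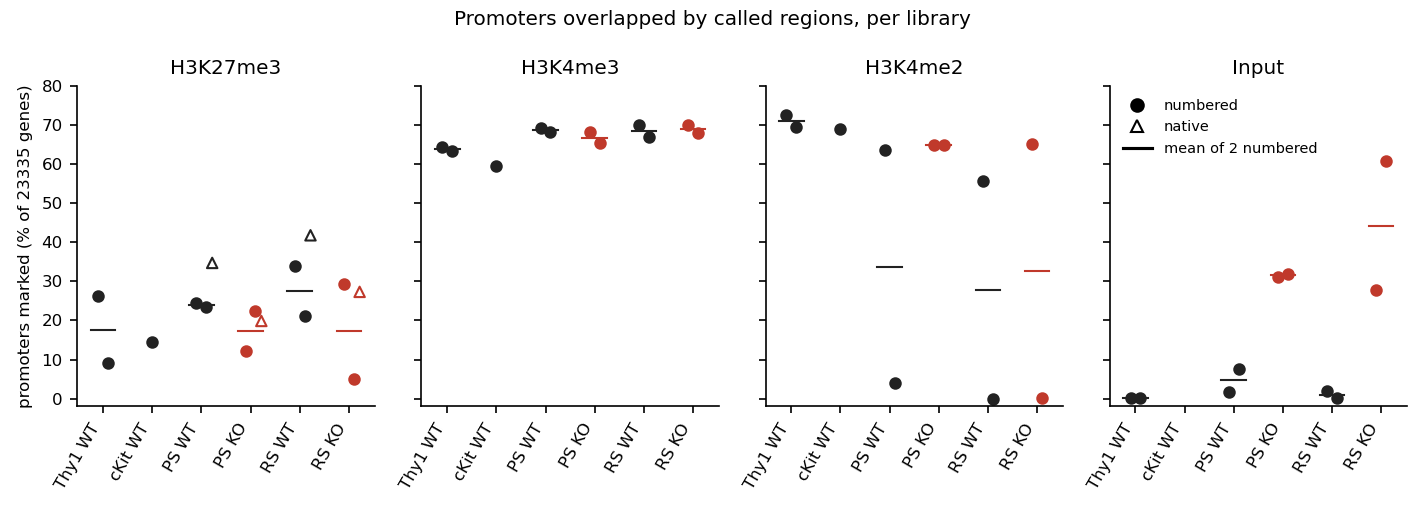
Share of 23335 gene promoters overlapped by a called region (vertical axis, %) in each library of each stage and genotype, for H3K27me3, H3K4me3, H3K4me2 and input; circles are numbered libraries, triangles native ones, bars the mean of 2 numbered libraries, WT black and KO red. H3K27me3 shares reach 41.8% in the native WT library of RS and 4.97% in the second KO library, and 3 H3K4me2 libraries lie below 4%.

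Developmental genes carried H3K27me3 in both genotypes, and the lists were not tested against each other. Hox genes were marked at 95.3% of members on average in WT and 91.5% in KO (−3.85 points), and Hoxa3, Hoxa5 and Hoxa6 were called in all 3 KO libraries of PS and of RS. Of 36 Hox promoters marked in every WT library of PS, 31 were marked in every KO library, and 33 of 36 in RS. For the other developmental transcription factors the counts were 116 of 161 and 123 of 166, and for developmental signalling genes 45 of 86 and 36 of 88. Hox genes lie near the ceiling of this measure, and an overlap of 1 bp does not show how much of a domain was covered. The other developmental transcription factors stood at 98.4% and 88.1% (−11.2 points). Within this list Tlx3 was called in every PS and RS library, while Meis1, marked in all WT libraries of both stages, was called in 1 of 3 KO libraries of PS and 2 of 3 of RS. Developmental signalling genes stood at 92.0% and 72.3% (−18.8 points). Of these, Fgf18, a fibroblast growth factor, was marked in all WT and 1 of 3 KO libraries of PS, and Slit3 in all WT and 2 of 3. Wnt5a, Bmp7 and Wnt9a were marked in all WT and 2 of 3 KO libraries of RS. Kdr and Fgf4 in PS and Wnt3a in RS were marked in all WT and all 3 KO libraries.

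Germ cell genes also had lower shares in KO. Spermatogonial genes stood at 69.0% in WT and 52.0% in KO (−17.1 points). Upp1 was called in all PS libraries and Dmrtb1, a regulator of the switch from mitosis to meiosis, in all WT and 1 of 3 KO libraries of RS. Meiotic genes stood at 14.9% and 8.62% (−6.68 points). Rec8, the meiotic cohesin, was called in all WT and 2 of 3 KO libraries of PS, and in all WT and 1 of 3 of RS. Spermatid genes differed by −15.3 points (27.4% and 14.2%), Sertoli cell markers by −16.3 (75.8% and 58.3%), and Leydig, peritubular, vascular and blood cell markers by −18.5 (44.8% and 30.5%). Polycomb genes, among them Cbx8, differed by −13.9 points (24.8% and 12.4%) and keratin genes by −17.3 (53.8% and 39.4%). Housekeeping genes differed by −1.96 points (2.62% and 0.952%), olfactory receptor genes stood at 6.25% and 6.05%, and Rhox genes at 0% in both.

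The means of WT and KO weigh each of 6 libraries alike, whereas the differences are averaged over stages and preparations, so the 2 need not match. None of the 13 lists passed an adjusted p of 0.05, and 0 passed unadjusted. Unadjusted, 6 lists passed an exact permutation p of 0.05 without RS KO 1 and 2 without PS KO 2. The lowest exact two-sided permutation p was 0.0833, for Polycomb genes (adjusted 0.271). Developmental genes against other autosomal genes within a library gave a KO minus WT log2 odds of −1.14 (exact permutation p = 0.139). That value turned to 0.62 (exact permutation p = 0.0556) when regions called in WT input were left out, and to 0.31 with the same number of regions per list. Numbered and native libraries differed within a genotype: Leydig, peritubular, vascular and blood cell markers stood in WT PS at 29.3% in the numbered libraries and 65.5% in the native one.

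**Figure D2:**
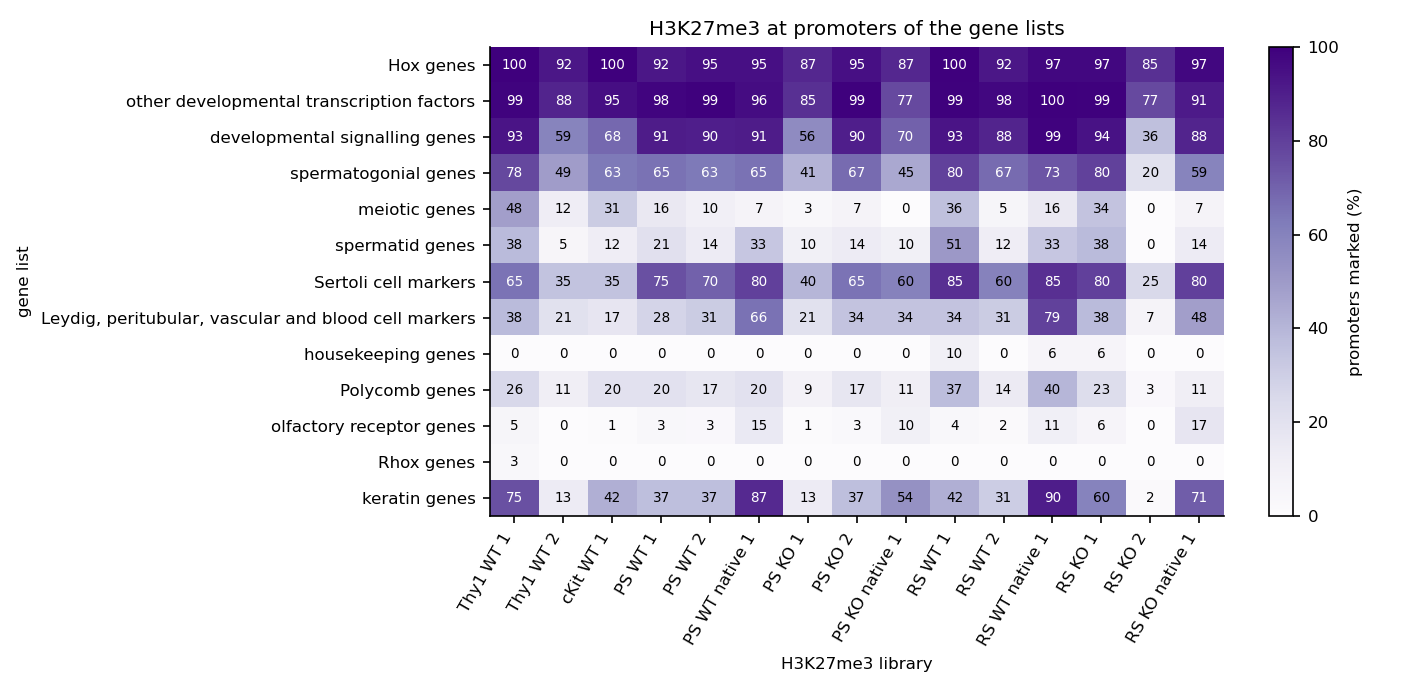
Percentage of the members of each fixed gene list (vertical axis) whose promoter carried H3K27me3 in each of the 15 libraries (horizontal axis), from white at 0% to dark purple at 100%. Hox genes stay between 85 and 100% in every library, while developmental signalling genes range from 36% in RS KO 2 to 99% in the native WT library of RS.

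Genes that had H3K27me3 in all 3 WT libraries and no KO library numbered 132 in PS, against 1 in the reverse direction. This balance depended on list length. In the numbered libraries it was 34 against 53 with the same number of strongest regions per list, and 27 against 21 with a fold of at least 4. None of the 132 belonged to a fixed list, while 1 to 29 list genes appeared with single libraries left out. None was X-linked, but PS WT 1 marked only 1 X-linked promoter in all, so this count was close to fixed. Ranked by the lowest fold in the WT lists, they began with 4931440F15Rik and Gng11, a G protein gamma subunit (NM_025331, chromosome 6, 4003987 to 4008446, folds 6.92 and 25.5 in the numbered lists). Syngr2, Zfp219, a zinc finger protein, and Gm806 followed in the ranking. Ckap4, Prrt3, Sec31b, Dhrs4 and Cst6 were named too, as were Ski, a corepressor of TGF-beta signalling (NM_011385, chromosome 4, 155154075 to 155222535, folds 3.45 and 3.23), and Zfp36l2, which binds AU-rich messenger RNA. Slc52a3, a riboflavin transporter, and Acsl5, an acyl-CoA synthetase, were also among them.

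In RS the count was 41, with 0 in the reverse direction and none in a fixed list or on the X chromosome. With single libraries left out, 0 to 22 list genes appeared. The native WT library of RS marked 2 X-linked promoters in all. Prss8, a membrane-anchored serine protease (NM_133351, chromosome 7, 127925717 to 127930113), led with folds of 10.2, 5.46 and 4.66, followed by Itpripl1 and Zfp219. Dhdh, Gm10857, Pnma1, Fam83g, Rgl2 and Nckap5l were also named. So were Gm4532 and Zfp553, neighbours with the same folds in each list. Nid1 encodes the basement membrane protein nidogen, Lmnb2 a nuclear lamin, Coasy the enzyme of the last steps of coenzyme A synthesis and Slc12a1 a renal chloride cotransporter. The stages shared 12 genes, among them Ski, Syngr2, Zfp219, Lmnb2, Nckap5l and Gm10857. Among the 4409 promoters marked in every WT library of both stages, 69 and 19 genes would share 0.297 if the lists were independent. They need not be, since promoters near the limit of calling can be missed in both stages without an effect of genotype. The shared genes therefore do not show a loss repeated between stages.

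These counts rested on single libraries. Without PS WT 1 the PS count was 213, without PS WT 2 it was 320, without PS KO 2 851 and without the native KO library 227. Without RS WT 2 the RS count was 433, without RS KO 1 573 and without the native KO library 81. Of the promoters marked in every WT library, 2125 of 4827 (44.0%) in PS and 1101 of 4801 (22.9%) in RS were marked in every KO library. RS KO 2 marked 1160 promoters in all, which caps the RS count.

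Bivalent promoters followed the H3K27me3 share. Of the promoters with H3K4me3 in PS, 31.7%, 30.5% and, in the native library, 35.0% also had H3K27me3 in WT, against 16.3%, 28.9% and 21.4% in KO. In RS the values were 43.5%, 27.3% and 42.7% in WT and 36.8%, 6.72% and 28.4% in KO. Among the 309 developmental genes, 87.4%, 87.7% and 84.1% were bivalent in WT PS and 64.1%, 80.3% and 59.5% in KO PS, while RS had 84.8%, 82.2% and 84.8% in WT and 85.1%, 56.0% and 77.0% in KO. The KO minus WT difference was −12.5 points, with a lower KO mean in each stage and preparation and an exact two-sided permutation p of 0.0556. It was −16.3 points (exact permutation p = 0.0139) without RS KO 1, −8.77 (exact permutation p = 0.139) without RS KO 2 and −1.62 (exact permutation p = 0.667) with the same number of regions per list. In the numbered RS libraries the lower KO mean rests on RS KO 2, since RS KO 1 lies above the WT mean of 35.4%. The difference between stages gave an exact permutation p of 0.861.

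Few X-linked promoters overlapped an H3K27me3 region in either genotype. In the WT libraries of PS the X share was 0.198% ± 0.140 (SD, n = 2) in the numbered libraries and 0.890% in the native one, and in KO it was 0.198% ± 0.140 (n = 2) and 0.0989%. In RS the WT shares were 1.78% ± 1.96 (n = 2) and 0.198%, and the KO shares 1.98% ± 2.80 (n = 2) and 0.0989%. Thy1+ cells had 4.95% ± 5.32 (n = 2) and the c-Kit+ library 2.87%. Input lists also held few X-linked promoters: in KO PS 1.19% and 1.68% of X-linked against 32.5% and 33.4% of autosomal promoters, and in KO RS 0.396% and 6.23% against 29.0% and 63.4%. Against autosomes, the KO minus WT log2 odds was −0.19 (exact two-sided permutation p = 0.778). Its sign was not stable: it was 0.27 without either native library of PS, 0.05 without RS WT 1 and 0.24 without RS KO 2.

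**Figure D3:**
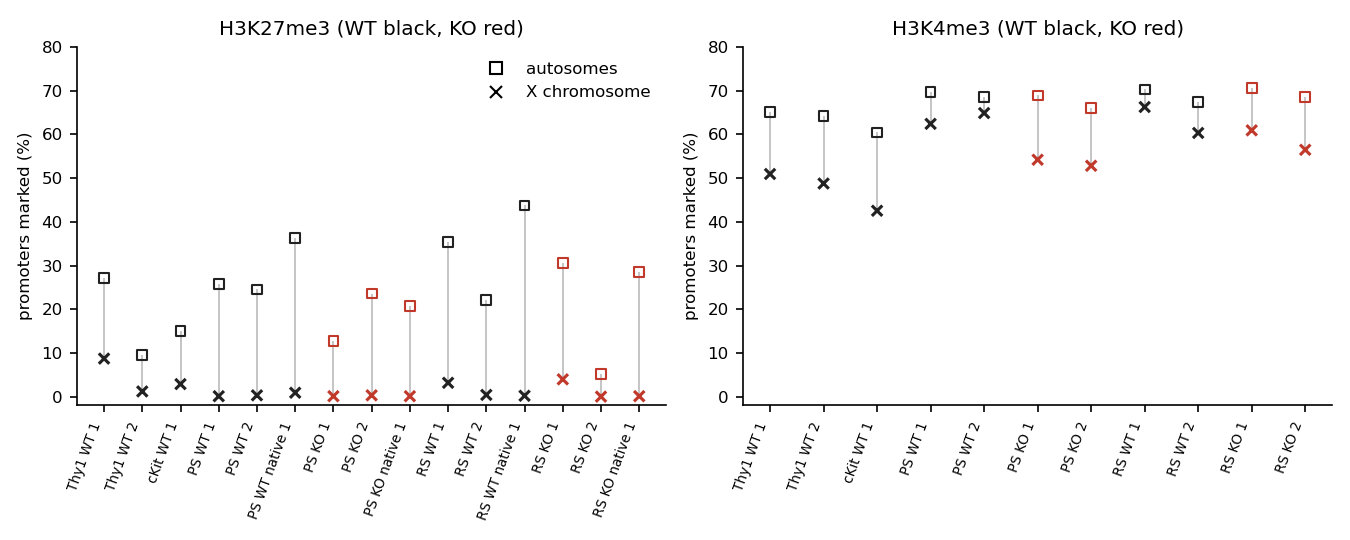
Share of autosomal promoters (squares) and X-linked promoters (crosses) with H3K27me3 (left) and H3K4me3 (right) in each library (vertical axis, %; WT black, KO red; lines join the values of a library). H3K27me3 crosses lie at or below 3.96% in every PS and RS library, while H3K4me3 crosses lie between 52.8% and 66.3% in the same stages.

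H3K4me3 at promoters was close between genotypes. In PS 68.8% ± 0.673 (SD, n = 2) of promoters were marked in WT and 66.8% ± 1.97 (n = 2) in KO, and in RS 68.5% ± 2.14 (n = 2) and 69.0% ± 1.57 (n = 2). Tfap2b and Myf5, regulators of neural crest and of muscle, Rhox9, Rhox2h and the olfactory receptor genes Olfr281 and Olfr126 were called in both WT and no KO library of PS. Apof, Hist1h4n, Tmem176a, Tmem176b, Gbp3 and Olfr463 were called in both KO and no WT library of PS. In RS Fgf14, Myf5, Dppa3, a germ cell and oocyte factor, and 3 olfactory receptor genes were called in both WT and no KO library, and Tagln, a smooth muscle gene, Apoa1, Igfn1, Gm14327, Glrx and Olfr15 in both KO and no WT library. The full counts were 202 and 23 in PS and 123 and 113 in RS.

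The KO minus WT difference in the H3K4me3 share was −0.769 points, with an exact two-sided permutation p of 0.556 (smallest possible 0.0556, so this design cannot reach 0.05). It turned to 3.76 points with a −log10 q of at least 5 and to 3.85 with a fold of at least 4. The second WT list of PS is the H3K4me3 list without summits.

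H3K4me2 could not be compared with the same weight, because 3 of the 8 lists were short. Where lists were long, 63.6% (PS WT 1), 64.8% and 64.8% (PS KO), 55.7% (RS WT 1) and 65.1% (RS KO 1) of promoters were marked. In PS, 441 promoters were called in both KO libraries and no WT library, and 0 the other way. PS WT 2 marked 910 promoters in all, so few could be called in both WT libraries, and the 441 in effect sets the KO lists against PS WT 1 alone. No gene is named from it, nor from RS, where 2 of the 4 lists were short.

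The KO minus WT difference in H3K4me2 was 17.9 points (exact two-sided permutation p = 0.222, smallest possible 0.0556). It was 3.01 without PS WT 2, 4.01 without RS WT 2, 1.72 without RS KO 1 and 34.1 without RS KO 2, 32.9 without PS WT 1 and 31.9 without RS WT 1. Without the 3 short lists together, chosen after seeing the data, it was 5.30, and without the 2 lists of under 1000 regions it was 20.2.

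In c-Kit+ WT cells RNA levels were set against the promoter marks of the same cell type. Genes bivalent there had a median of 0.763 and 0.740 RPKM in the 2 libraries (2615 genes), and genes with H3K4me3 only 9.76 and 9.89 (11282 genes). Genes with H3K27me3 only (767) had 0.0757 and 0.0662 RPKM, and the median of the 8671 genes with neither mark was 0 in both. Some bivalent genes were abundant. Marks and RNA were read over all cells of a sample, and RNA of somatic markers was present too. The 2 marks and the RNA of such a gene may therefore come from different cells. Dazl, a germ cell RNA-binding protein, reached 410 RPKM ± 0.295 (SD, n = 2), Uchl1, a deubiquitinase of spermatogonia, 402 ± 44.6 and Mcam 186 ± 22.4. Sdc4, the basement membrane collagens Col4a1 and Col4a2, Mt2, Actg1 and Gnas were also among the 10 highest, with 154 to 296 RPKM. Rn45s, the ribosomal RNA precursor, had the highest value (463 ± 63.1), which is uncertain because its copies share reads.

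Gene groups differed in level. Hox genes had medians of 0.224 and 0.175 RPKM, with 25 of 39 bivalent and 9 at 1 RPKM or more in both libraries. Other developmental transcription factors had medians of 0.304 and 0.276 and 141 of 170 bivalent, Sox18, of the vascular endothelium, being the highest at 52.4 RPKM ± 7.41. Spermatogonial genes had medians of 22.6 and 23.0 RPKM, with 27 of 49 bivalent, and spermatid genes 0.0501 and 0.0526. Markers of somatic cells were also present: Cdh5 stood at 95.3 RPKM ± 11.0 and Pecam1 at 73.4 ± 11.3, both endothelial, Cyp11a1 of Leydig cells at 90.1 ± 15.5 and Clu of Sertoli cells at 122 ± 21.8. The promoters of Cdh5 and Pecam1 carried neither mark in the c-Kit+ lists, while those of Cyp11a1 and Clu carried H3K4me3. Of the Leydig, peritubular, vascular and blood cell markers 23 of 29, and of the Sertoli cell markers 17 of 20, had at least 1 RPKM in both libraries.

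The median log2(RPKM + 1) of bivalent genes lay −2.61 and −2.65 from that of genes with H3K4me3 only, −2.63 ± 0.03 (SD, n = 2). With 1 group there was no comparison between conditions, and genes are not independent replicates. The 2 libraries differed by more than sampling noise, with a chi-square of 12.5 per gene model over 15440 gene models. Libraries prepared separately from 1 sample would also exceed that noise, so this does not show separate samples.

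**Figure D4:**
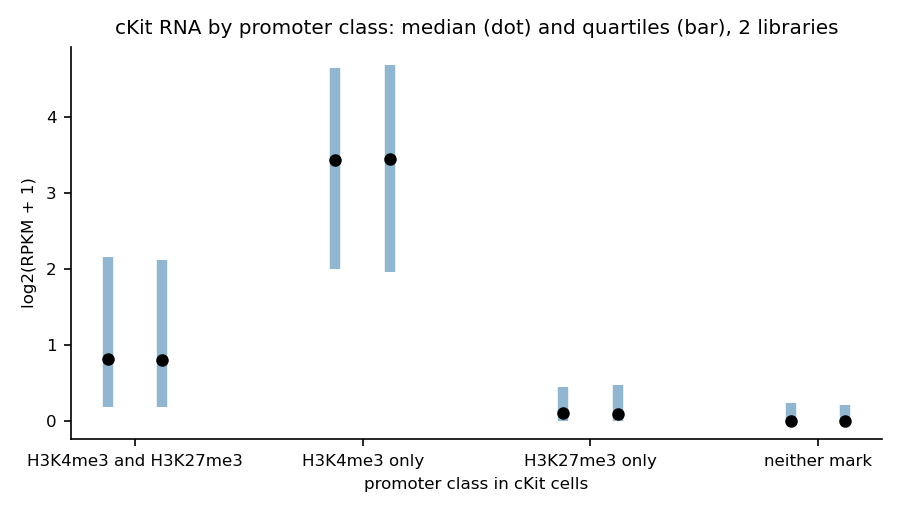
Median (dot) and quartiles (bar) of log2(RPKM + 1) in the 2 RNA libraries of c-Kit+ WT cells (vertical axis) for genes grouped by their promoter marks in c-Kit+ cells (horizontal axis). Bivalent genes have medians of 0.82 and 0.80 and genes with H3K4me3 only 3.43 and 3.45.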

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

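The comparisons of the knockout input lists, the counts on the X chromosome at a doubled fold, the reading of list background and the other divisions of the libraries were tests chosen only after the results were seen. The setting with the same number of regions per list had been fixed before.

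In the KO input lists many promoters overlapped a called region: 31.1% and 31.9% in PS and 27.7% and 60.8% in RS, against at most 7.65% in WT input. The KO minus WT difference was 35.0 points (exact two-sided permutation p = 0.0556, the smallest possible of 36). Deeper sequencing would raise the background, which was 1.16 times the WT value in PS for 8.09 times the regions (1.54 and 52.8 in RS), and this speaks against depth alone. An H3K4 library under an input label should mark X-linked promoters. The highest X share in a KO input was 6.23%, and the lowest in the 19 H3K4 lists other than the 3 short ones 18.1%. The short H3K4me2 list PS WT 2, with 3.90% of promoters marked, had 0.0989% of X-linked and 4.08% of autosomal ones. Its log2 odds of −4.84 lay within the −6.51 to −4.69 of the KO inputs. A weak H3K4 library is therefore not excluded by the X share. An H3K27me3 library under that label should leave housekeeping genes unmarked, yet at least 30% of them were marked, against at most 10% in any H3K27me3 list. A different fragmentation or setting of the calling was not tested, nor was a property of KO chromatin, and no animal or batch is named that would separate them.

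Few X-linked promoters had H3K27me3 in PS and RS. A single X copy should bring X-linked promoters to the share that autosomal ones keep at 2 times a low fold of the list, the 5th percentile of its marked autosomal promoters. In the 3 spermatogonial libraries the ratio of these shares was 0.780 on average (0.690 to 0.862), near the value of 1 that a single copy would give. In the 4 numbered WT libraries of PS and RS it was 0.115 (0.0370 to 0.208; exact two-sided permutation p = 0.0286 between stages), which a single copy does not account for. Exceptions were RS KO 1 with 0.627 and the native KO libraries with 3.15 and 2.20, where only 0.0314% and 0.0449% of autosomal promoters passed the doubled fold. Poor recovery of X chromatin stays open: the lowest KO input ratio was 0.947, but in 3 of the 4 inputs it rests on 0.418% to 0.485% of autosomal promoters, and over all regions the KO inputs were poor in X-linked promoters too (log2 odds −5.27 and −4.83 in PS, where H3K27me3 lists had −7.86 to −5.91, and −6.51 and −4.69 in RS, where they had −8.30 to −3.40). The H3K4me3 of 63.5% ± 2.63 (SD, n = 4) of X-linked promoters in WT PS and RS, against 47.4% ± 4.36 (n = 3) in spermatogonia, argues against a loss of all X signal, but a partial loss would leave strong regions called. A different chromatin state of the silenced X chromosome in meiosis and a property of the calling were not tested.

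Fewer promoters had H3K27me3 in the KO lists. If lower depth were the cause, libraries with a higher KO background should show no deficit, but in the 3 such sets of the same stage, preparation and number the difference was −6.65 points on average (SD 7.02), and −14.3 in the other 2. Depth is therefore not settled. If weaker enrichment of whole libraries were the cause, equal numbers of regions should remove the deficit: with 3353 strongest regions per list it was −1.60 points (exact permutation p = 0.667), against −10.5 (exact permutation p = 0.111) with all regions of the same 10 libraries. Weaker immunoprecipitation and a loss of H3K27me3 over many promoters would both do this and cannot be told apart here. Whether input served as a control in the calling is not given. In the native lists with usable values, 99.6% to 100% of rows had 1 same background, which argues against a control that varied by position there. In the numbered lists 79.3% to 94.2% of rows did, which leaves the question open for them. What the KO input lists, with 27.7% to 60.8% of promoters, meant for the KO calls was not tested, since the input filter used WT input only.

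The counts of genes marked in every WT and no KO library were compared with the other ways to divide the 6 libraries of a stage. With 10 divisions there are too few for a share under 0.05. In PS the real division gave 132 genes and the highest other 106, so 1 of 10 reached the real count. That division also sets the PS lists with the most marked promoters (WT, 5465 to 8103) against those with the fewest (KO, 2822 to 5253). List size alone could therefore rank it first, and its rank does not speak for genotype. In RS it gave 41 and the highest other 519, and 4 of 10 reached the real count. The 519 came from RS WT 1, the native WT library and RS KO 1 against the rest, which points to a structure of the samples, the lists with the most marked promoters, stronger than genotype.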

How the results depend on the processing

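Of 197 alternatives to the main results, 158 left the sign and the call, a count or a difference about in place. Another 4 gave a stronger call, 13 reversed the sign and 22 moved a value, and the cause was not tested. Among the 158, 13 for H3K4me3, 16 for H3K4me2 and 15 for X-linked H3K4me3 could have changed the sign but not the call. The smallest exact permutation p possible in those tests was 0.0556, which misses the threshold. A further 10 concerned the RS minus Thy1+ difference in H3K27me3, which had no call. They ran from 1.21 to 18.4 points against 9.83, so the 158 overstates how stable the results were. A call in place says little of size: the H3K27me3 share difference was −1.60 points with the same number of regions, and the X-linked H3K4me3 log2 odds −0.11 with a −log10 q of 5. With the replicate block the H3K27me3 share difference of −11.6 points was −10.6 (exact p = 0.0313, the smallest that the block allows). With single libraries left out it was −14.6 to −8.53, reaching an exact p of 0.0139 without RS KO 1. The bivalent difference was −12.0 (exact p = 0.0313, again the smallest possible) with the block and −16.3 to −8.77 with single libraries left out. The labels do not tie libraries of the same number to each other. Deviations of same-number libraries correlated at 0.0937 in PS and 0.209 in RS for H3K27me3. The values were 0.25 and 0.221 for H3K4me3, and −0.0117 and 0.799 for H3K4me2, short lists included. Background in the PS and RS H3K4me3 lists of both genotypes was 1 to 1.12 for number 1 and 0.375 to 0.429 for number 2. The number thus went with a difference between libraries, and what it stands for was not tested.

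The X log2 odds for H3K27me3 turned to 0.64 (500 bp overlap), 3.59 (−log10 q of 5), 2.64 (fold of 4), 1.01 (same number of regions) and 0.29 (numbered libraries), and ran from −0.61 to 0.27 with single libraries left out. The H3K4me3 share turned to 3.76 (−log10 q of 5) and 3.85 (fold of 4) points. The developmental log2 odds turned to 0.31 (same number) and 0.62 (WT input regions out). H3K4me2 ran from 1.72 to 34.1 points with single libraries left out; the same number of regions was not run for it, as the shortest list has 2.

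The 132 genes of PS became 37 (−log10 q of 5), 27 (fold of 4), 34 (same number), 296 (numbered libraries) and 465 (at least 2 WT libraries), and 144 to 851 with single libraries left out. Of the first 3 sets only 5, 2 and 5 genes were among the 132. The reverse count of PS, 1 in the main setting, became 19 (−log10 q of 5), 21 (fold of 4), 53 (same number) and 9 (numbered libraries). With the same number of regions the balance thus turned, 34 against 53, while in RS the reverse count stayed at 0 in these settings. With 2.5 kb 69 of 143 and with 500 bp of overlap 37 of 155 were, and in RS 24 of 35 and 14 of 41 were among the 41. The 41 of RS became 55 (−log10 q of 5, 0 shared), 95 (fold of 4, 1 shared), 16 (same number, 0 shared), 93 (numbered libraries) and 447 (at least 2 WT libraries), and 41 to 573 with single libraries left out. The first 3 settings leave out the native pair of PS. No gene list passed an adjusted 0.05 in any of 21 alternatives, while unadjusted 6 did without RS KO 1, 2 without PS KO 2 and 2 with the block. The c-Kit+ RNA difference of −2.63 was −2.57 (2.5 kb), −2.57 (500 bp), −2.25 (−log10 q of 5), −2.13 (fold of 4), −3.54 (pseudocount of 0.1) and −2.23 (RPKM of at least 0.1), and −2.65 to −2.61 with single libraries left out.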

Other observations

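The tests of H3K4me3 on the X chromosome were chosen only after the result was seen.

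X-linked promoters had H3K4me3 less often in KO than in WT. The X share in PS was 62.4% and 64.9% in WT and 54.2% and 52.8% in KO, and in RS 66.3% and 60.3% in WT and 60.9% and 56.5% in KO. Rhox genes stood at 41.9% and 38.7% in WT and 16.1% and 12.9% in KO of PS, and at 45.2% and 25.8% against 25.8% and 9.68% in RS. Of the 202 promoters with H3K4me3 in both WT and no KO library of PS 50 were X-linked, Rhox9 and Rhox2h among them, and of the 23 in the reverse direction 1. In RS the X-linked counts were 25 of 123 and 1 of 113.

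Against autosomes the KO minus WT log2 odds was −0.41 (exact two-sided permutation p = 0.0556, the smallest possible), with −0.50 in PS and −0.33 in RS. If unequal list lengths were the cause, equal numbers of regions should remove it, but with 38727 per list it was −0.46 (exact permutation p = 0.0556). That is the length of PS WT 2, the list without summits, which stayed whole at −0.24 while PS WT 1 went from −0.47 to −0.65. In PS this setting therefore does not settle the matter. In RS, where every list was shortened, the values were −0.48 and −0.71 in WT and −0.89 and −1.10 in KO. It was −0.11 (exact permutation p = 0.722) with a −log10 q of at least 5 and −0.13 (exact permutation p = 0.667) with a fold of at least 4, settings that also filtered the PS list without summits, and what made it smaller there was not tested. One hypothesis is that H3K4me3 on the X chromosome of germ cells is lower without SCML2, a weaker enrichment in the KO libraries being the alternative. Counting reads over the same X-linked promoters in every library, scaled to autosomal promoters, would test it.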
